A study of Mus musculus with 8 samples.

How the data were processed

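CUT&Tag libraries of DC-SCRIPT from splenic cDC1 and cDC2 of female C57BL/6 mice, wild type and lacking Zfp366, were grouped by subset and genotype from their titles: 3 wild-type and 2 knockout libraries of cDC1, and 1 wild-type and 2 knockout libraries of cDC2. Each library was a pool of mice, per the labels. The authors deposited 2 tables, each with the peaks of 1 subset.

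Peaks were called with HOMER findPeaks in its factor mode on 1 wild-type tag directory with 1 knockout tag directory as control, per the file headers, so no library was called alone. Whether every library of a group entered its directory is not given in the sources used here. The header of the cDC1 table gives a peak size of 191 bp, a false discovery rate of 0.001, at most 1 tag per position, a fold over knockout of at least 4 with a Poisson p of at most 0.0001, and the same limits against the surrounding 10 kb. The cDC2 header gives the same limits. From 174971 putative peaks in cDC1, the knockout removed 64.5% (exact 95% interval 64.3% to 64.7%) and the local signal 17.5%, which left 31473. From 19569 in cDC2, the knockout removed 79.3% (exact 95% interval 78.8% to 79.9%) and the local signal 6.47%, which left 2776. Of all wild-type tags, 6.47% lay in peaks in cDC1 and 0.79% in cDC2, per the file headers. The submitters' processing notes name HOMER and builds GRCm38 and mm10, which are names of the same assembly. The aligner, read trimming and the treatment of duplicate reads are not given in the sources used here.

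The deposited signal of a peak is its wild-type tag count scaled by the authors to a total of 10000000 tags, called normalised tags here. The deposited tags behind the fold are given at the knockout depth in cDC1 and at the wild-type depth in cDC2, and were scaled back to unscaled tags here. The deposited score is HOMER's own, in tags of the wild-type set, and is not scaled to depth, so scores were ranked within a list only. The focus ratio, a fraction between 0 and 1 per the file headers, was read and not used. The deposited fold is the ratio of wild-type to knockout tags at equal depth, and a second ratio compares the peak with its surroundings. Each deposited p-value is the authors' Poisson p over tags, not over replicates. Of the columns, 1 on clonal tags was not used.

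The depth of the knockout sets, 12.1 M and 6.83 M tags, was worked out here from the scaling between the columns. It sets the precision: a knockout count of 3 tags equals 2.47 normalised tags in cDC1 and 4.40 in cDC2. The lowest knockout value, 0.5 tag, also stands for no tag. It was listed at 6329 cDC1 and 382 cDC2 peaks. There only the exact lower 95% limit of the fold is given, with no knockout tag. Other folds carry an exact (Clopper-Pearson) 95% interval of the tag ratio, with tags rounded to whole numbers. The limit of 1 tag per position did not hold for these tags. At Hip1 in cDC1, 846.3 wild-type tags stood against a score of 288. Those tags are more than 191 bp can hold at 1 tag per position on each strand. Repeated tags were counted as separate, so intervals may be too narrow. Molecular identifiers are not given in the sources used here, so intervals and limits cover counting error and no spread between mice.

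The design allowed for tests per library. Since the tables hold the authors' peaks only, no test between genotypes was made here. Each peak was assigned to the protein-coding gene that contains its centre, or else to the gene with the nearest end, from a RefSeq gene table of assembly GRCm38.p6 with 21883 protein-coding genes. That table gives no strand and no exons, so gene ends are named lower and upper by coordinate, and the planned promoter, intron and exon classes were replaced by position inside a gene, within 1 kb of a gene end, and over 10 kb from any gene. The same classes were counted for 4 random moves of all cDC2 peaks and of 5000 cDC1 peaks. A planned search for 17 transcription factor motifs was not run, because no genome sequence was used here.

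These choices were made before the data were examined: the 12 gene lists, the rule for named genes, the tests and most alternatives. Named genes were Zfp366, Irf8 and Il12b with their peaks, the 10 genes with the highest-scoring peaks per subset, up to 4 genes per list with the highest-scoring peaks, and the 10 shared regions assigned to a gene with the highest cDC2 score; other members of a list were named after their values were seen. The lists held 275 entries. Their genes were matched by symbol, 2 of them by a synonym (Septin3 and Rtl8a). Mx1 and Mx2 are not protein-coding in the table and were left out. 11 genes stood in more than 1 list. Some genes are not reported here by name. Each list was tested with Fisher's exact test, two-sided, against all protein-coding genes, with Benjamini-Hochberg adjustment over the 12 lists per subset. Beside it, 10000 random lists of the same size were drawn, matched gene by gene on territory, the length of chromosome nearest to the gene, in 50 classes. The smallest p these can give is 0.0002. For the difference between subsets, random genes were matched on their highest cDC1 signal in 40 classes. Overlap of cDC2 with cDC1 peaks by at least 1 bp was tested against 100000 placements with each cDC2 peak moved by 50 kb to 500 kb, one-sided. Scores of shared and unshared cDC1 peaks were compared by a permutation test with 100000 resamples.

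Alternatives were a fold of at least 8, a p under 1e-10, autosomes, an overlap of 50% or centres within 1 kb, the 50% of peaks with the higher scores, moves of 5 kb to 50 kb, and the fold in place of the score. Added after the data were seen were peaks within 10 kb or 100 kb of a gene in place of start sites, and cDC1 tags thinned at random to the cDC2 depth in 100 draws, with the cDC2 limits applied again. In a further thinning, wild-type and knockout densities were also multiplied by 0.838 and 1.79, the cDC2 to cDC1 ratios of summed tags at shared peaks, which had passed the cDC2 limits. The gene lists used 1 draw.

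The procedures were tested on simulated data made from the real peaks and genes. Lists of 25 genes given an odds ratio of 4 were found in 7 of 8 cases by both list tests. Of 100 unchanged lists of genes with long territories, Fisher's exact test called 28 and matched random lists called 0, so matched values are given wherever they change a call. Random placements of 2775 cDC2 peaks were called in 0 of 100 overlap tests. The fold interval covered 98.4% of simulated 10-fold peaks, drawn without the authors' limits. Listed peaks had passed those limits, so this coverage need not hold for folds near 4. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.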

Results

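The binding of DC-SCRIPT, a zinc finger protein of dendritic cells encoded by Zfp366, was profiled by CUT&Tag in conventional dendritic cells from mouse spleen. CUT&Tag directs a transposase to an antibody-bound protein, so that DNA near the protein is cut, tagged and sequenced. Both splenic subsets were sorted from female C57BL/6 mice: cDC1, which take up dead cells and cross-present antigen to CD8 T cells, and cDC2, which prime mainly CD4 T cells. Knockout animals lacking Zfp366 served as the background control. The 8 libraries comprised 3 wild-type and 2 knockout mouse pools of cDC1, and 1 wild-type and 2 knockout mouse pools of cDC2. For each subset a list of peaks was available in which wild-type signal exceeded knockout signal, made from 1 set of wild-type tags and 1 set of knockout tags. The wild-type set held 35.5 M tags in cDC1 and 4.77 M in cDC2, and the knockout set held 12.1 M and 6.83 M. Signal is given as normalised tags, which are tags in a peak scaled to a total of 10000000. No value per library was used here, so no spread between mouse pools could be given. The score, fold and p of each peak are the authors' own, and intervals around a fold were computed here from the tags and cover counting error only. Coordinates refer to mouse build GRCm38.

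The first comparison asked where DC-SCRIPT was bound in cDC1, as signal present in wild-type cells and reduced in knockout cells. The cDC1 list held 31473 peaks, and 10 of them were assigned to Zfp366 itself, 6 to Irf8 and 14 to Il12b. Irf8 encodes the transcription factor that specifies cDC1, and Il12b encodes the p40 subunit of interleukin 12. Zfp366 lies on chromosome 13 from 99184823 to 99247032. Its highest peak, at 99182107 to 99182297, lay 2.62 kb below the lower gene end and reached 58.1 normalised wild-type tags, with a fold over knockout of 36.0 (95% interval 9.82 to 298.5, 2 knockout tags). Inside the gene, the peak at 99211074 to 99211264 held 29.9 normalised wild-type tags and knockout tags at the lowest value listed, and the exact lower 95% limit of its fold was 9.66. Which part of the gene was deleted is not given in the sources used here, and a site within a deleted part would lose its tags whether or not it was bound.

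Around Irf8, on chromosome 8 from 120736358 to 120756694, the 2 highest peaks lay beyond the upper gene end. They stood at 120763436 to 120763626 and at 120768609 to 120768799, which is 27.2 kb and 32.3 kb above the lower gene end. The first reached 51.3 normalised wild-type tags and a fold of 13.9 (95% interval 6.01 to 58.1), and the second 50.7 tags and a fold of 13.7 (95% interval 5.91 to 57.1). A peak next to the lower gene end, at 120736070 to 120736260, was weaker, at 14.8 tags and a fold of 4.49 (95% interval 1.64 to 16.9). The Il12b gene lies on chromosome 11 from 44400063 to 44414677. Its highest peak, at 44417543 to 44417733, lay 2.96 kb beyond the upper end, with 69.5 normalised tags and a fold of 24.1 (95% interval 8.11 to 77.8). Next to that end, the peak at 44414903 to 44415093 held 47.9 tags with a fold of 30.1 (95% interval 8.21 to 250.5). Another peak of 49.3 tags, at 44183852 to 44184042, lay 216.1 kb below the gene, and had Il12b as its nearest protein-coding gene.

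**Figure D1:**
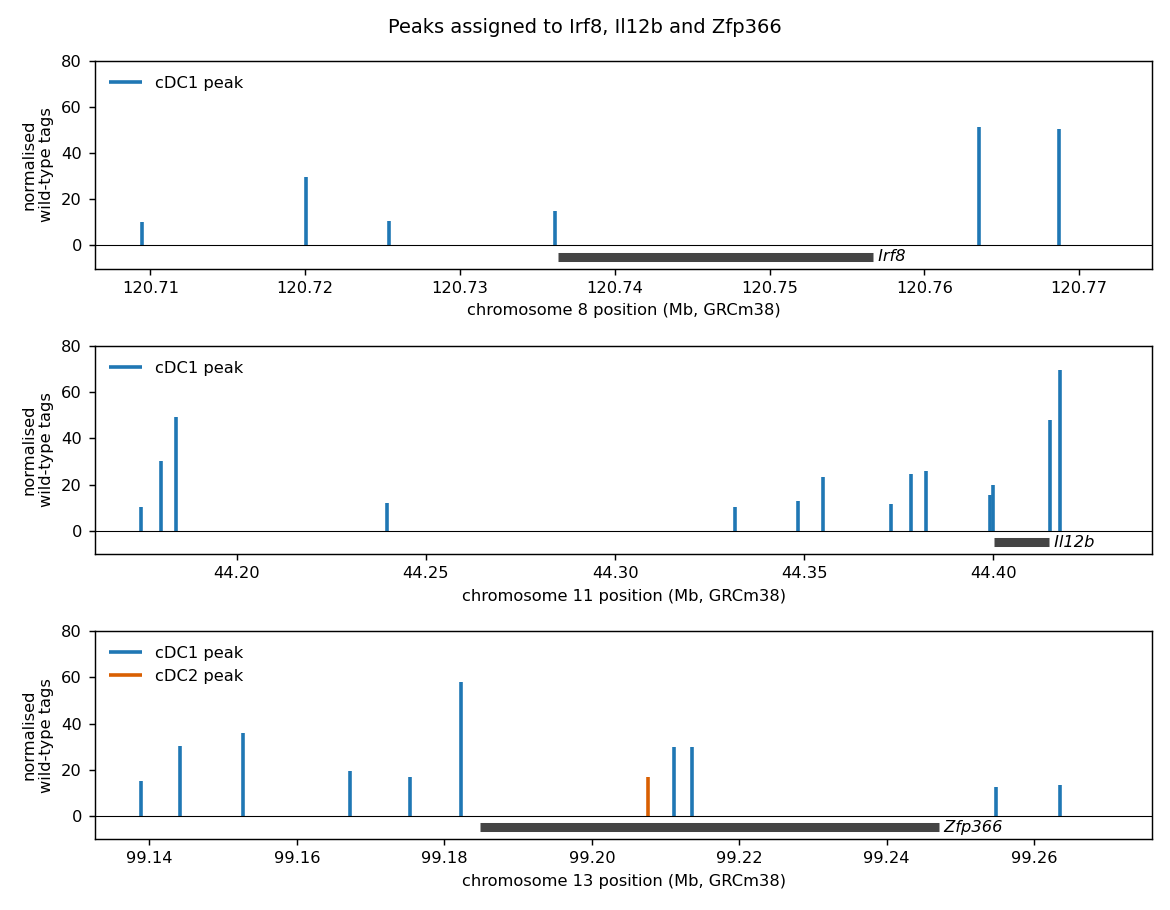
Peaks assigned to Irf8, Il12b and Zfp366, with position in Mb on the horizontal axis and normalised wild-type tags on the vertical axis; each bar is 1 peak, blue for cDC1 and orange for cDC2, and the dark bar below the axis is the gene. Irf8 and Il12b carry 6 and 14 cDC1 peaks and no cDC2 peak, and Zfp366 carries 10 cDC1 peaks and 1 cDC2 peak.

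The 10 genes with the highest-scoring cDC1 peaks were Tnc, Atp1b3, Hip1, Cnpy1, Ptpn3, Cadm1, Ubash3b, Gtf3c5, Cep295 and Acoxl. Tnc encodes the matrix protein tenascin-C, and its peak inside the gene on chromosome 4 at 64009734 to 64009924 scored 302, with 184.4 normalised wild-type tags and a fold of 150.3 (95% interval 31.1 to 932.7). The Atp1b3 peak on chromosome 9 at 96399503 to 96399693 scored 294.5 and lay 35.2 kb beyond the gene, which encodes a subunit of the sodium pump. Its fold was 132.2 (95% interval 36.5 to 1094). Hip1 followed with a score of 288, 238.2 normalised tags and a fold of 34.1 (95% interval 18.3 to 84.1). Cadm1, an adhesion molecule that marks cDC1, had a peak of 203.7 normalised tags inside the gene, at 47734137 to 47734327 of chromosome 9, with a fold of 35.3 (95% interval 17.0 to 88.1). Ubash3b, Gtf3c5 and Cep295 held peaks of 216.4, 176.4 and 115.6 normalised tags. Over all 31473 peaks the median was 15.5 normalised wild-type tags and the median fold 10.2, with quartiles of 6.72 and 16.8. Every fold is at least 4 because the authors required it, so the list cannot show regions without a difference.

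Genes of dendritic cells carried cDC1 peaks more often than other genes. The list tests, here and in cDC2, compare with all protein-coding genes, expressed or not. Beyond the knockout limits, they cannot tell binding of DC-SCRIPT from open DNA at active genes. All 25 genes of the list of core dendritic cell genes and transcription factors had at least 1 cDC1 peak, against 50.8% of the 21883 protein-coding genes (Fisher's exact test, adjusted p = 7.56e-07). They carried 202 peaks together, among them Id2 with 32, Hlx with 21, Etv6 with 18 and Bcl11a with 18. The highest peaks of Etv6 and Zbtb46, the latter a transcription factor of the conventional lineage, reached 102.3 and 78.7 normalised tags, and that of H2-Aa, a class II chain, 95.4. Of the 25 genes that mark cDC1, 24 had a peak (exact test, adjusted p = 9.75e-06), and the exception was Rtl8a. Cadm1, Bcl6, Wdfy4 and Tlr3 had the highest-scoring peaks of this list. Bcl6, a transcriptional repressor, carried 20 peaks, the highest with 124.9 tags and a fold of 38.2 (95% interval 14.8 to 140.9). Wdfy4, required for cross-presentation, reached 84.4 tags, and Tlr3, a sensor of double-stranded RNA, 102.8 tags. Batf3 and Xcr1, a transcription factor and a chemokine receptor of cDC1, each carried 5 peaks.

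Genes that mark cDC2 were also near cDC1 peaks, 20 of 25 (exact test, adjusted p = 0.00847). Prdm1 with 24 peaks and Klf4 with 21 carried the most. The highest-scoring peak was that of Itgam, which encodes CD11b, with 73.2 normalised tags, and Prdm1 reached 73.4. The call for this list ended when only the 50% of peaks with the higher scores were used (Fisher's exact test, adjusted p = 0.0678, with a range of 0.0031 to 0.0678 over its alternatives). Among cytokine and costimulation genes, 25 of 29 had a cDC1 peak (exact test, adjusted p = 0.000432). Their highest peaks were those of Cd86 with 89.8 tags, Il1b with 83.7, Cd83 with 80.6 and Icosl with 74.4. Ebi3, Il23a, Cxcl10 and Cd70 had none. For genes of antigen processing and presentation the count was 19 of 25 (exact test, adjusted p = 0.0255), with Psmb9, an immunoproteasome subunit, at 93.6 tags and H2-DMb1, which takes part in class II peptide loading, at 80.6. H2-K1, B2m, Tap1 and Tap2 were among the 6 without a peak. Several genes of this list, among them H2-Oa, Psmb9, Tap1, H2-Aa and H2-Eb1, lie between 34092379 and 34316674 of chromosome 17. The list tests count such neighbours as independent. Of the interferon and Toll-like receptor genes, 24 of 30 had a cDC1 peak (exact test, adjusted p = 0.00442), among them Ifngr1 with 139.1 tags, Ifnar2 with 116.6 and Irf5 with 114.3, while Isg15, Ifit1 and Ifit3 had none.

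Markers of other cells in the spleen gave mixed counts in cDC1. Peaks lay near 14 of 16 plasmacytoid dendritic cell markers (exact test, adjusted p = 0.00847), including Ccr9 with 53.4 tags and Runx2 with 42.2. That call ended with the higher-scoring 50% of peaks (exact test, adjusted p = 0.19) and with cDC1 tags thinned to the depth of cDC2 (adjusted p = 0.272). Over its alternatives the adjusted p of the exact or permutation test ran from 0.00378 to 0.272. The counts did not differ from other genes for T and NK cell markers with 12 of 22, B cell markers with 10 of 17, monocyte, macrophage and neutrophil markers with 14 of 22, or erythroid markers with 7 of 12 (exact tests, adjusted p = 0.832, 0.756, 0.383 and 0.832). Cd79a, Lck, Zap70, Lyz2 and the globin genes Hba-a1 and Hbb-bs had no peak. Neuron and liver genes had peaks less often than other genes, 7 of 25 (exact test, adjusted p = 0.0403), a call that ended with the higher-scoring peaks (adjusted p = 0.4) and with thinned tags (adjusted p = 0.738). Over the alternatives of this list the adjusted p of the exact or permutation test ran from 0.00395 to 0.738. Apoa2, Cyp7a1 and Map2 were among the 7, at 55.5, 33.4 and 27.2 normalised tags. Random lists matched on the length of chromosome nearest to each gene gave the same 8 calls, with adjusted p from 0.0008 to 0.0237.

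**Figure D2:**
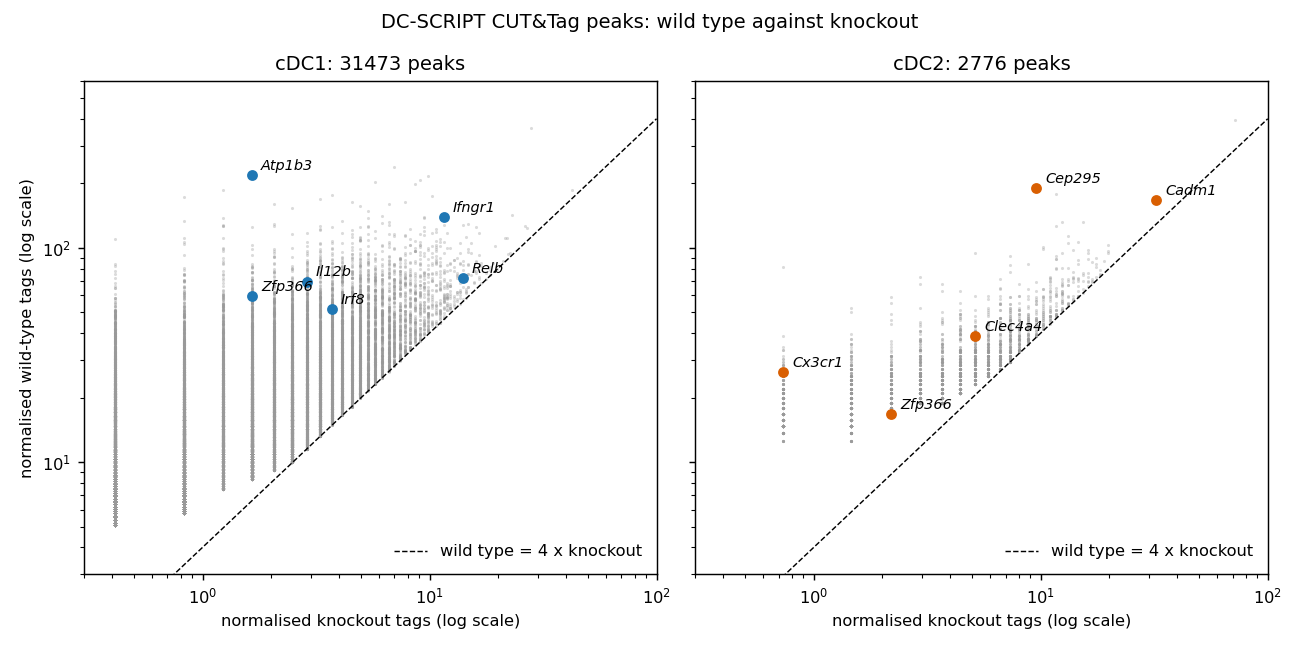
Normalised wild-type tags (vertical, log scale) against normalised knockout tags (horizontal, log scale) for each peak of cDC1 (left, 31473 peaks) and cDC2 (right, 2776 peaks), both from the tags behind the authors' fold; the dashed line marks the 4-fold difference the authors required and coloured points are the highest peaks of named genes. The leftmost column of points holds the 6329 cDC1 and 382 cDC2 peaks with knockout tags at the lowest value listed.

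The same question was asked of cDC2, where 2776 peaks had wild-type signal above knockout. Of the peaks assigned to a gene, the highest-scoring were those of Cep295, Atp1b3, Zbtb3, Pxdc1, Cadm1, Ier5, Ifnar2, Gtf3c5, Cass4 and B4galnt1. The peak assigned to Cep295, a centrosomal protein gene, lay 37.7 kb beyond it on chromosome 9, at 15395445 to 15395635, and reached 189.5 normalised wild-type tags and a fold of 19.9 (95% interval 9.47 to 60.0). The peak next to Zbtb3 on chromosome 19 at 8802200 to 8802390 reached 178.0 tags with a fold of 15.3 (95% interval 7.46 to 36.7). Cadm1 followed with 166.5 tags and a fold of 5.17 (95% interval 3.21 to 8.75), and Ifnar2, a chain of the type I interferon receptor, with 98.4 tags and a fold of 9.60 (95% interval 4.31 to 25.2). Zfp366 carried 1 peak, inside the gene at 99207466 to 99207656, with 8 wild-type tags, 1.5 knockout tags and a fold of 7.62 (95% interval 1.14 to 55.3). No cDC2 peak was assigned to Irf8 or Il12b. With cDC1 tags thinned to the cDC2 depth, the 2 highest Irf8 peaks passed the cDC2 limits in 99% and 100% of draws. The highest Il12b peak passed in 100%. With the cDC2 tag densities at shared peaks as well, the same Irf8 peaks passed in 83% and 74% of draws, and the Il12b peak in 99%. At depth alone, other peaks passed in as few as 15% of draws at Irf8 and 22% at Il12b. Of all cDC1 peaks that passed at depth alone, 90.6% were absent from the cDC2 list, so absence at these genes is not particular to them. A difference between subsets at these genes was not tested. The median over the list was 24.1 normalised tags and the median fold 7.42. A single wild-type pool stands behind this list, and no replicate check of it exists.

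In cDC2, 15 of the 25 core dendritic cell genes and transcription factors had a peak, against 9.44% of all protein-coding genes (Fisher's exact test, adjusted p = 6.31e-09). Itgax, which encodes CD11c, reached 47.1 normalised tags, Etv3 48.2, Zbtb46 40.8 and Etv6 37.7. Of the cDC2 markers, 13 of 25 had a peak (exact test, adjusted p = 4.79e-07). The highest-scoring peaks were those of Clec4a4, a lectin of cDC2, at 38.7 tags with a fold of 7.56 (95% interval 2.12 to 26.1), Ltb at 32.5, Itgam at 30.4 and Cx3cr1 at 26.2, where knockout tags were at the lowest value and the exact lower 95% limit of the fold was 3.97. Irf4, Klf4 and Zeb2, transcription factors of cDC2, carried 2 peaks each, and Notch2 carried 1. The cDC1 markers had a peak at 8 of 25 genes (exact test, adjusted p = 0.00465), with Cadm1 at 166.5 tags, Bcl6 at 88.0, Rab7b at 40.8 and Xcr1 at 37.7. Interferon and Toll-like receptor genes counted 10 of 30 (exact test, adjusted p = 0.00113), with all 4 interferon receptor genes among them: Ifnar2 at 98.4, Ifngr1 at 64.9, Ifnar1 at 57.6 and Ifngr2 at 39.8 tags.

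Cytokine and costimulation genes had a cDC2 peak at 7 of 29 (exact test, adjusted p = 0.0387), with Tnfsf9 at 50.3 normalised tags, Cd83 at 45.0, Pdcd1lg2 at 39.8 and Ccl5 at 38.7. This call ended against territory-matched random lists (permutation test, adjusted p = 0.0552) and with only peaks within 10 kb of the gene (exact test, adjusted p = 0.143), in a range of 0.00225 to 0.143 over its alternatives. The other 4 lists kept their call against matched lists (permutation test, adjusted p from 0.0008 to 0.033). The antigen presentation genes with a peak were Ciita, the class II transactivator, and Cd1d1, 2 of 25, which did not differ from other genes (exact test, adjusted p = 1). None of the remaining lists passed, with 1 of 22 T and NK cell markers, 4 of 17 B cell markers, 3 of 16 plasmacytoid markers, 2 of 22 monocyte, macrophage and neutrophil markers, 0 of 12 erythroid markers and 1 of 25 neuron and liver genes (exact tests, adjusted p = 0.86, 0.139, 0.321, 1, 0.826 and 0.762).

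**Figure D3:**
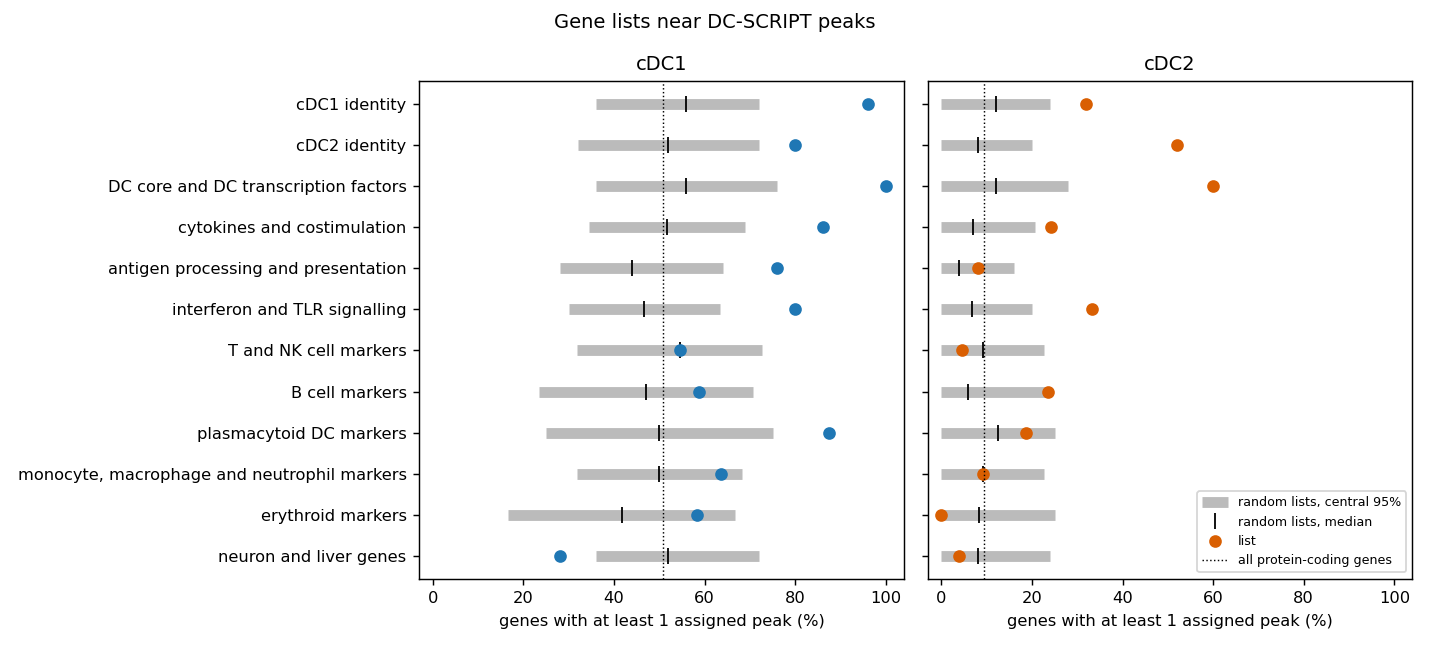
Percent of the genes in each list with at least 1 assigned peak (horizontal axis) for the 12 lists (vertical axis) in cDC1 (left, blue) and cDC2 (right, orange); grey bars span the central 95% of 10000 random lists matched on territory length, black ticks are their medians and the dotted line is the percent over all protein-coding genes, 50.8% in cDC1 and 9.44% in cDC2. Core dendritic cell genes stand at 100% in cDC1 and 60% in cDC2, above the grey bars in both.

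A further comparison asked whether the peaks of both subsets lay at the same places. Of the 2776 cDC2 peaks, 1767 overlapped a cDC1 peak by at least 1 bp, which is 63.7% (exact 95% interval 61.8% to 65.4%). Of the shared regions assigned to a gene, the 10 with the highest cDC2 scores belonged to the 10 genes named for cDC2. The region near Atp1b3 held 131.9 normalised tags in cDC2 and 217.9 in cDC1, that of Cep295 189.5 and 115.6, that of Pxdc1 131.9 and 42.0, and that of B4galnt1 102.6 and 27.2. When each cDC2 peak was moved by 50 kb to 500 kb, a mean of 25.8 peaks overlapped. The highest of 100000 placements gave 48 (permutation test, one-sided, p = 1e-05, the smallest that many placements can give). Moved peaks fall on any sequence, open to the transposase or not. The test therefore cannot tell shared binding of DC-SCRIPT from DNA that is open in both subsets. The remaining 1009 cDC2 peaks had no cDC1 peak at the same place, a count of 604 when centres within 1 kb counted as shared and of 1407 with an overlap of 50% of the shorter peak.

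The cDC1 peaks with more tags were more often listed in cDC2. Among cDC1 peaks split into 10 groups by wild-type tags, the share that overlapped a cDC2 peak ran from 0.425% in the lowest group to 19.3% in the highest (exact 95% intervals 0.233% to 0.713% and 18.0% to 20.8%). The 3 lowest groups held at most 10.9 normalised tags, below the 12.6 of the weakest peak listed in cDC2, so the depth of cDC2 limits this comparison. The median score of shared cDC1 peaks was 78 and that of the others 44 (permutation test, two-sided, p = 1e-05). Peaks are not replicates, so this p describes the lists only. Across the 1767 shared regions, the median wild-type signal was 31.3 normalised tags in cDC1 and 26.2 in cDC2. The median knockout signal was 2.47 and 4.40 normalised tags, which is 3 tags in each knockout set. The median fold was 14.4 in cDC1 and 6.83 in cDC2.

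**Figure D4:**
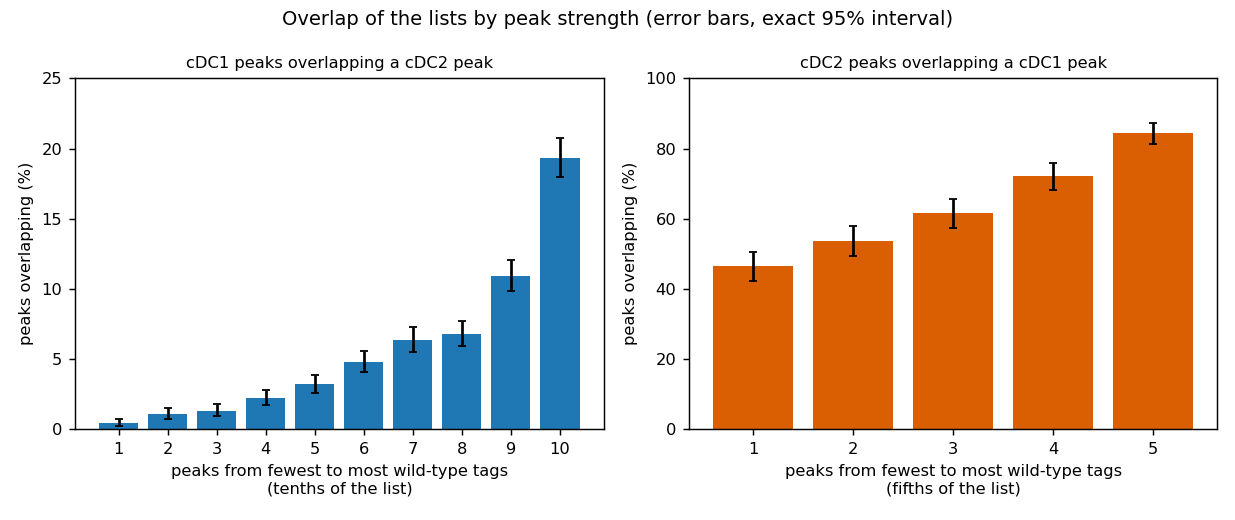
Percent of cDC1 peaks that overlap a cDC2 peak (left) and of cDC2 peaks that overlap a cDC1 peak (right), vertical axes, for groups of about equal size ordered from the fewest to the most wild-type tags, horizontal axes; error bars are exact 95% binomial intervals. The percent rises from 0.425% to 19.3% on the left and from 46.4% to 84.5% on the right.

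The positions of the peaks relative to genes were compared between cDC2 peaks and the cDC1 peaks that were not shared. Peaks centred inside a protein-coding gene made up 56.4% of 29696 unshared cDC1 peaks and 50.1% of 2775 cDC2 peaks (Fisher's exact test, adjusted p = 5.94e-10). Peaks centred within 1 kb of a gene end made up 21.1% and 16.8% (exact test, adjusted p = 1.04e-07), and peaks over 10 kb from any gene 24.2% and 28.4% (exact test, adjusted p = 1.44e-06). These tests count peaks, which are not replicates, and the cDC2 list rests on 1 wild-type pool. Peaks moved by 50 kb to 500 kb lay within 1 kb of a gene end in 4.60% of cDC1 and 4.87% of cDC2 placements. Inside genes lay 51.9% and 52.1% of the placements, so the cDC2 share of 50.1% was not above them. Over 10 kb from any gene lay 34.7% and 34.4%. Peaks within 1 kb of a gene end included those next to Ifngr1, H2-DMb1 and Irf8 in cDC1 and those next to Zbtb3, Itgax, Itgam and Clec4a4 in cDC2.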

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

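The tests of list differences and of the chromosome Y peaks were chosen after the results were seen, and the thinning and common-loss tests after the lists had been looked at, with the bounds that decide between the explanations fixed before those tests were run.

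In the comparison between subsets, 11 of the 20 cDC2 marker genes with a cDC1 peak also had a cDC2 peak, against 17.6% of all genes with a cDC1 peak (Fisher's exact test, adjusted p = 0.00103). Random genes matched on their highest cDC1 signal gave a median of 4 (central 95% 1 to 8, permutation test, adjusted p = 0.0168). Klf4, Irf4, Zeb2, Notch2, Itgam and Ltb were among the 11. Core dendritic cell genes had 15 of 25 (exact test, adjusted p = 3.03e-05), where matched genes gave 9 (4 to 13, permutation test, adjusted p = 0.0876). Interferon and Toll-like receptor genes had 10 of 24 (exact test, adjusted p = 0.0199), where matched genes gave 8 (4 to 13, permutation test, adjusted p = 1). For cDC1 markers the count was 8 of 24, with 9 in matched genes. Antigen processing and presentation genes had 2 of 19, where matched genes gave 6 (3 to 10, permutation test, adjusted p = 0.118). A direct comparison of the cDC1 and cDC2 marker lists did not pass (Fisher's exact test, two-sided, p = 0.223).

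Peaks were also listed on chromosome Y and on contigs. The cDC1 list had 10 peaks on chromosome Y and the cDC2 list had 6, and the mice were female. The cDC1 ones lay between 90738071 and 90819863. Knockout tags stood at the lowest value in 7 of the 10, against 20.1% of the other cDC1 peaks (Fisher's exact test, p = 0.000893), and in 3 of the 6 in cDC2, against 13.7% (exact p = 0.0375). The peaks lie within 81.8 kb in cDC1 and 82.1 kb in cDC2 and are not replicates, so both p-values describe the lists only. The first of the chromosome Y peaks held 38.6 normalised wild-type tags in cDC1 and 79.6 in cDC2. Mid1, a gene on X at the edge of the pseudoautosomal region, carried 14 cDC1 and 4 cDC2 peaks. The cDC1 peaks ran from 169544959 to 170005269 and the cDC2 peaks from 169980788 to 170012963. How many of them lie in the pseudoautosomal region was not counted. X and Y share the sequence of that region, so peaks listed there on Y can stem from X. Which chromosome these tags came from was not tested. Unplaced or unlocalised contigs held 11 cDC1 peaks and 1 cDC2 peak. The peak with the most tags in either list was on such a contig, with 360.9 normalised tags in cDC1 and 393.7 in cDC2.

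The cDC2 list was shorter than the cDC1 list, 2776 against 31473 peaks, and thinned to the cDC2 depth, 14171 cDC1 peaks passed on average (14016 to 14347 in 100 draws), so depth alone accounts for part of the gap. With the cDC2 densities at shared peaks as well, 7801 passed (7639 to 7953). Shared peaks had already passed the cDC2 limits, which biases this count upwards, so higher knockout density stays open although the bound set before was exceeded. It, fewer bound regions in cDC2, or a weaker enrichment of its single wild-type pool may account for the rest, and 1 pool cannot tell these apart. Of the cDC1 peaks that passed in the first thinning, 90.6% were absent from the cDC2 list, a share largely set by the lengths of the lists, which decides nothing.

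At every listed peak the knockout was lower, as the authors required for listing, which one common loss of signal in the knockout set could produce. Within 20 ranges of wild-type tags, the interval of the fold excluded the median of its range at 11.5% of the 6614 cDC1 peaks with at least 100 tags. In 20 simulations with 1 fold per range it did so at 2.38% on average (1.98% to 2.72%). The simulation, revised after its first result had been seen to draw both genotypes and to be repeated, holds counting noise only, and the spread between mouse pools is not known, so the excess does not speak against a common loss although the bound set before was exceeded. No biological explanation was tested.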

How the results depend on the processing

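Alternatives chosen after the data were seen are the thinned tags, the distances of 10 kb and 100 kb, and autosomes for the overlap. A fold of at least 8 left 20109 cDC1 and 1262 cDC2 peaks, and a p under 1e-10 left 17913 and 443, each fewer by construction. Thinned tags left 14171 cDC1 peaks, and 7801 with the cDC2 densities at shared peaks. Overlap stayed above the random placements under all 5 alternatives, from 49.3% (50% of the shorter peak) to 78.2% (centres within 1 kb). The strength of shared peaks and the 3 position classes kept their direction and call. With the higher-scoring 50% of peaks the class differences (cDC2 minus unshared cDC1) grew, from -6.30 to -10.1 percentage points inside genes, from -4.25 to -10.1 near gene ends and from 4.19 to 9.66 far from genes. Of the single lists and the other position classes, 103 results kept their side of the threshold and 7 lost their call. No list with a call turned direction. Erythroid markers in cDC1 and antigen presentation genes in cDC2, both without a call, each changed sign in 3 alternatives. The number of lists above background ran from 5 to 7 in cDC1 and 4 to 5 in cDC2. No paired analysis was possible because values were deposited per genotype and subset and not per library. For the same reason no library was left out in turn, and tests on counts or values per library were not run. Distances from start sites and motif windows were not run, since strand and sequence were not used here. The weakest listed peak held 12.6 normalised tags in cDC2, from 4.77 M wild-type tags, and 4.51 in cDC1, so weaker cDC2 sites were not detectable at this depth.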

Other observations

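The tests of shared marker peaks, of the relation across shared regions and of the region around Zfp366 were chosen after the results were seen. Some genes carried clusters of peaks. In cDC1, Foxp1 carried 45 peaks, Jarid2 41, Lpp 34, and Id2 and Adgrl2 32 each. Foxp1, Jarid2, Id2, Bach2 and Prdm1 encode regulators of transcription, and Bach2 and Prdm1, known from B cell differentiation, carried 26 and 24. Atp2b1 with 30 and Foxn3, Marcks, Reep3 and Snx29 with 26 each also ranked high. Whether any class of genes was more frequent among the clusters was not tested. Per length of chromosome, Foxp1 had 4.80 peaks per 100 kb and Id2 5.14, against 1.38 for Adgrl2. In cDC2, Tomm20 carried 7 peaks, Akap13, Id2 and Tet2 carried 6 each, and Bcl6 was among the genes with 5. Prdm1 had no cDC2 peak. These genes, and those of the next paragraph, were chosen after their values were seen.

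Among the 1009 cDC2 peaks that overlapped no cDC1 peak (604 had no cDC1 centre within 1 kb), the 7 highest-scoring lay in or near Ptpn3, Grb2, Plekhg3, Vasp, Aff1, Fos and Rbpj. The one inside Ptpn3, on chromosome 4 at 57306259 to 57306449, held 72.3 normalised wild-type tags with a fold of 4.83 (95% interval 2.50 to 11.6). The peak below Fos, an immediate early transcription factor, held 50.3 tags and a fold of 13.7 (95% interval 4.26 to 149.7). That of Rbpj, the nuclear partner of Notch, held 56.5 tags. The Grb2 peak had a fold of 4.09 (95% interval 2.04 to 9.14). Clec4a4 and Dtx1, a Notch pathway gene, had a cDC2 peak and no cDC1 peak of their own. The Dtx1 peak held 14.7 normalised tags, close to the 12.6 of the weakest peak listed in cDC2. Of the cDC2 peaks near cDC2 markers, 12 of 19 were shared, and of those near cDC1 markers 16 of 19 (Fisher's exact test, two-sided, p = 0.269).

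Across the 1767 shared regions, wild-type tags in cDC1 and cDC2 rose together (Spearman rho 0.596). For the fold over knockout rho was 0.0740, where folds start at 4 and rest on few knockout tags. Both are across regions, which are not independent replicates.

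A hypothesis formed after seeing the peaks at Zfp366 was that sequence linked to the targeted allele could add peaks over a wide region. Between 1 Mb and 5 Mb from the gene lay 151 cDC1 peaks, at the 74.1 percentile of the same count around other genes, and within 1 Mb 55, at the 75.4 percentile. Both counts were above the medians around other genes, 116 and 38. At these percentiles, a wide excess beyond that around many other genes was not seen.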
